A study of Mus musculus with 4 samples.

How the data were processed

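The olfactory epithelium of CD-1 mice, an outbred strain, was profiled by single-cell RNA sequencing at postnatal days 0, 3, 7 and 21 (P0, P3, P7 and P21), with 1 library at each of the 4 ages. The tissue lines the nasal cavity and holds the olfactory sensory neurons (OSNs), the basal cells that replace them, and supporting, glandular and stromal cells. Per the labels' protocols, cells were freed with papain, loaded as sorted samples on a Chromium controller and made into 3' libraries with unique molecular identifiers (UMIs). The gate of that sort, the number and sex of the mice behind each library and the day of each preparation are not given in the sources used here. The labels aim at 2000 to 3000 cells per library and state 1400 to 3000 captured cells and 20000 to 50000 reads per cell; the deposited tables hold 2703, 3220, 1787 and 1416 cells at P0, P3, P7 and P21.

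The deposited values are counts of UMIs per gene and cell, whole numbers that the authors had not normalized. The submitters' processing notes name Cell Ranger 2.1.1, Seurat and the mouse genome build mm10. Which of these made the tables, the gene annotation they used, and any filter on cells before deposit are not given in the sources used here. Depth was 9207027 UMIs at P0, 17770838 at P3, 8653791 at P7 and 6861044 at P21, with medians of 3221, 4982, 4681 and 4410 UMIs and 1651, 2196, 2132 and 2006.5 genes per cell. Of 49671 gene symbols in the tables, 47313 (95.3%) were found in the GENCODE annotation of the same build, which gave coordinates.

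Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which removed 12, 0, 2 and 2 cells. A further limit of 10% haemoglobin UMIs, set after the data were seen, removed 1 cell at P21 whose haemoglobin reads had given a basal cell cluster the name of another type. Scrublet, run per library in scanpy, marked 27, 7, 8 and 1 cells as doublets, which were removed. It marked too few cells in all to be taken as working, so doublets remain in the data; an alternative removed the 58, 83, 25 and 16 cells with the highest scores, 0.8% per 1000 cells. This left 2664, 3213, 1777 and 1412 cells with 9032294, 17697664, 8547200 and 6839278 UMIs.

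Cells of all 4 libraries were clustered together without batch correction, on log-normalized values of 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1.0. Clusters were named from 21 marker sets fixed before the data were examined, and names end in "-like". A name needed at least 3 detected markers. How markers were weighed was set after the data were seen. The set with most markers among a cluster's 10 leading genes gave the name, and where none or several led, the set with the highest score, which is the mean log2 level of its markers (20 CPM added) relative to the median cluster. The score had to be at least 1.0 and, in such a tie, 0.5 above the next, and a cluster with 3 or more sets scoring 2.5 or above stayed unnamed. By these rules cluster 3 carried both the mature and the immature OSN set and was kept out of either class, and cluster 19, led by leukocyte genes such as Cd74 and S100a8, stayed unnamed. OSNs were clustered again on 20 components at resolution 0.6.

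For expression, UMIs were summed per library and class and scaled to CPM, the usual share of each sum. Changes are log2((CPM + 10 at P21)/(CPM + 10 at P0)), and ratios of CPM carry exact conditional binomial intervals at 95%. Levels carry exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals. All intervals cover counting error only. With 1 library per age there is no replicate check of any difference and no test across libraries; age and library cannot be separated, and each comparison is one between libraries. A gene was measured with at least 50 CPM and 20 UMIs in the P0 or the P21 library.

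Named genes follow a rule set before the data were examined, as were 20 gene lists plus the lists of all odorant receptor (Olfr) and trace amine receptor (Taar) genes. In mature-OSN-like cells, immature-OSN-like cells and all cells, the rule takes the 10 measured genes with the largest and the 10 with the smallest change, then 5 in each direction whose CPM moved the same way at each step, then 5 with the highest level at P3 or P7 relative to both ends. Mitochondrial, ribosomal protein and haemoglobin genes, Xist, Y genes and glandular genes are left out of this ranking, and Omp and Gap43 are always given. Sustentacular-like cells had 14 cells at P21, under the 30 the rule asks for, and were not compared. Because single receptor genes filled most of the ranking in mature cells, the same rule was also run without Olfr genes, a choice made after the data were seen. A list member counts as higher or lower when it differs at least 1.5-fold and its interval excludes 1, among members with at least 20 UMIs in either library. A list's median is given with its percentile among 10000 random lists of the same size, matched on expression in 20 bins. Taar genes were not measured in any of the 3 sets of cells.

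For receptors, each cell was thinned to 1500 UMIs, shallower cells were left out, and a receptor counted as present at 3 or more UMIs of 1 Olfr gene. The number of different leading receptors was taken over 100 draws of 100 cells. Because the deposited counts can split reads between near-identical genes, the last 300 bases of each measured gene's transcript were searched with blastn against the other transcripts; of 8956 genes searched, 1587 had a stretch of at least 80 bases at 95% identity or more in another gene. Genes with low counts over all cells were not searched, among them E330020D12Rik, Fcer1a, Gm9847, Gm37194, Hbb-bs, Nlrp14 and Obp2a, nor were symbols without a transcript in the annotation. Whether counting used the strand is not given in the sources used here; of 253 genes in the lists or named by the rule, 48 have exons that overlap a gene on the opposite strand and 9 a gene on the same strand, and these cannot be told apart from their partners. Among the genes named, this holds for 1700097N02Rik, Atf5, Bbs4, Bcl2, Cebpa, Cebpb, Ctnnbip1, Cwc22, Dynlt1a, Emx2, Gnal, Gng3, H1fx, Hddc2, Hopx, Igf2, Jun, Jund, Lrrc3b, Meg3, Mllt11, Ncam1, Nfia, Nfix, Pcsk2, Sfrp2, Syn1, Syp, Tmem181a, Wdr83 and Xist.

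The gene comparison was run on simulated Poisson counts, drawn from the class means without variation between cells or libraries. Such counts check the calculation and not how far real counts spread, so the coverage of the intervals was set by the design. In mature-OSN-like cells (3336 genes), the list rule called 60.0% of genes made 0.667-fold in the right direction. It called 100% of those made 0.25-fold, 3-fold or 4-fold and 0.221% of unchanged genes, and 94.9% of intervals held the true ratio. In immature-OSN-like cells (3556 genes) these were 68.0%, 100%, 1.95% and 95.1%. A 0.667-fold change lies at the limit of that rule, which largely sets the first rate. At the 2-fold limit used for counts of genes, 62% of those made 0.25-fold passed in mature-OSN-like and 74% in immature-OSN-like cells. Of those made 3-fold 100% and 96% passed, and of those made 4-fold 100% in both. Splits of higher and lower genes may therefore lean toward higher ones. Alternatives covered the cell filters, doublets, clustering resolution, a gate on Omp and Gap43 UMIs in place of clusters, the scaling, pseudocount and count filters, P3 or P7 in place of P0, and receptor thresholds. Others, added after the data were seen, covered male cells alone, single clusters, each gene without its highest cell, and the clustering controls described with the other observations. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and blastn 2.17.0, with random seed 1.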

Results

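Transcripts were counted in single cells of the olfactory epithelium of CD-1 mice at P0, P3, P7 and P21, in 4 libraries, 1 per age. By its title, the series concerns a population of neurons needed for the olfactory map during a critical period, that is, for the ordered connection of OSNs to the olfactory bulb. After filtering, 2664 cells were used at P0, 3213 at P3, 1777 at P7 and 1412 at P21, with 9032294, 17697664, 8547200 and 6839278 UMIs. Omp (olfactory marker protein, chromosome 7, 98143359 to 98145502 in mm10) marks mature OSNs, and Gap43 (growth-associated protein, chromosome 16, 42248442 to 42340651) marks immature ones. Over all cells Omp stood at 879 CPM at P0, 598 at P3, 1224 at P7 and 3831 at P21, and Gap43 at 1351, 852, 1067 and 728 CPM.

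The first comparison asks how the neuronal lineage was made up at each age. Mature-OSN-like cells (clusters 0 and 1) were 13.1% of the cells at P0 (95% interval 11.9 to 14.5%), 10.6% at P3 (9.54 to 11.7%), 20.9% at P7 (19.1 to 22.9%) and 59.2% at P21 (56.6 to 61.8%). Progenitor-like cells, the globose basal cells and immediate neuronal precursors that give rise to OSNs, were 33.6% (31.8 to 35.4%), 33.4%, 25.9% and 9.35% (7.88 to 11.0%). Immature-OSN-like cells were 532 of 2664 cells at P0 (18.5 to 21.5%), 13.8% at P3 (12.7 to 15.1%), 22.0% at P7 (20.1 to 24.0%) and 8.85% at P21 (7.42 to 10.5%). At P0 most of them lay in cluster 8 (437 of 532) and at P21 most in cluster 2 (99 of 125). There were 1.52 immature per mature OSN-like cell at P0 (1.33 to 1.74), 1.31 at P3 (1.13 to 1.51), 1.05 at P7 (0.910 to 1.21) and 0.150 at P21 (0.123 to 0.181). The border between immature and progenitor-like cells depends on naming. Cluster 5 (330 cells at P0, 29 at P21) was named precursor-like from 1 leading marker, although the immature set scored higher (2.92 against 2.54). With doublets kept and cells clustered anew, the immature class held 808 cells at P0 and 183 at P21.

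As shares of the neuronal lineage alone (2107, 2116, 1316 and 1196 cells), mature-OSN-like cells made up 16.6%, 16.1%, 28.3% and 69.9%, progenitor-like cells 42.5%, 50.7%, 35.0% and 11.0%, and immature-OSN-like cells 25.2%, 21.0%, 29.7% and 10.5%. Cluster 3, with both OSN marker sets, held 12.4%, 8.06%, 5.23% and 7.29% of all cells and 15.7%, 12.2%, 7.07% and 8.61% of the lineage. Among other cells, stromal-like cells took 6.68%, 15.5%, 9.12% and 0.779% (11 cells at P21), and horizontal basal cell-like cells, the reserve stem cells of the tissue, 1.35%, 4.08%, 4.45% and 4.60%. Sustentacular-like cells, the supporting cells around OSNs, were 1.46%, 0.218%, 3.38% and 0.992%. The unnamed cluster 19, led by leukocyte genes, held 32, 41, 17 and 19 cells. The labels speak of sorted samples without stating the gate, so each share can be set by the sort as well as by the tissue. The P21 share of mature-OSN-like cells exceeded the P0 share by 46.1 percentage points. It did so by 24.2 without the limits on genes, mitochondrial and haemoglobin UMIs, with called doublets still removed. Those limits had removed only 12, 0, 2 and 2 cells and 1 more at P21, but all cells were then clustered and named anew. The share thus depends on how clusters form and are named. The immature share differed by -11.1 points, but by -19.2 with a gate. Omp, one of the markers behind the class, was itself higher in the mature-OSN-like cells of the P21 library. A gate on at least 2 Omp UMIs in cells thinned to 1500 UMIs, which needs no clusters, gave 20.9%, 15.5%, 26.5% and 66.1% mature cells.

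**Figure D1:**
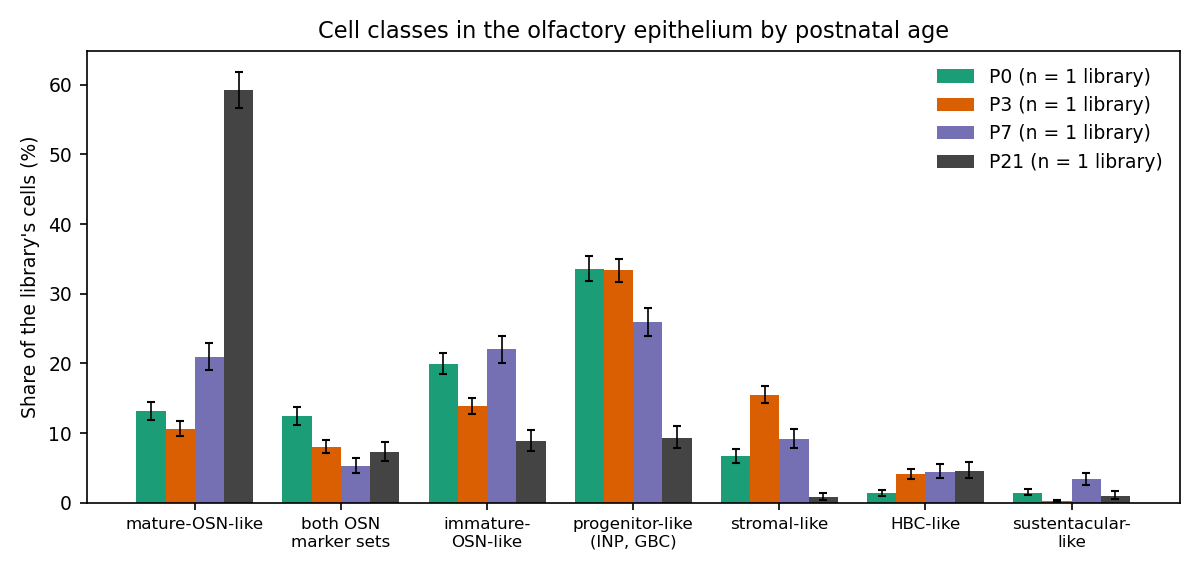
Share of each library's cells (percent, vertical axis) in 7 cell classes, with 1 bar per library and exact 95% binomial intervals that cover counting error only. Mature-OSN-like cells stand at 59.2% in the P21 library against 10.6 to 20.9% in the other libraries.

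When the 4176 cells with OSN names were clustered again, they fell into 9 subclusters. In 3 of these at least 80% of the cells came from 1 library, and these 3 held 1544 of the 4176 cells (37.0%). Of the 1212 P0 cells, 1015 (83.7%, interval 81.5 to 85.8%) lay in them. Of these, 544 lay in a subcluster with 2678 CPM of Omp and 1429 CPM of Gap43, and 470 in one with 161 and 4126 CPM. At P21, 452 of 1064 cells (42.5%, 39.5 to 45.5%) lay in a mature subcluster that was 96.8% P21 cells. A subcluster with intermediate Omp (3385 CPM) and Gap43 (1087 CPM) held 27.7% of the P3 OSNs, 22.0% at P7, 9.30% at P21 (7.63 to 11.2%) and 0.908% at P0 (0.454 to 1.62%). An immature one held 1.49% at P0, 41.1% at P3, 30.3% at P7 and 10.6% at P21. A low-depth mature subcluster held 6.85% of OSNs at P0, 17.4% at P3, 25.7% at P7 and 33.1% at P21. A cluster mostly of 1 library may be that library and not a cell type, so no subcluster is read as present at 1 age.

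The second comparison concerns expression within mature-OSN-like cells, with 350, 340, 372 and 836 cells and 1401397, 1669385, 1766243 and 3612450 UMIs at P0, P3, P7 and P21. In the P21 library these cells had more mRNA for the odour response and for some axon sorting molecules, and less for growth cone proteins. Cnga4, a subunit of the olfactory cyclic nucleotide-gated channel, stood at 255, 288, 314 and 639 CPM (P21 over P0 2.51-fold, 2.24 to 2.81). Kirrel2, an adhesion molecule that sorts OSN axons by their activity (chromosome 7, 30447534 to 30457690), stood at 176, 169, 213 and 609 CPM (3.46-fold, 3.03 to 3.96). Gap43 stood at 226, 316, 209 and 79.4 CPM (0.351-fold, 0.298 to 0.413), and Marcksl1, an actin regulator of the growth cone, at 253, 302, 196 and 78.9 CPM (0.312-fold, 0.266 to 0.366). A subcluster mostly of P0 cells held 259 of the 350 cells at P0 and 6 of the 836 at P21. One mostly of P21 cells held 1 and 451 of them. Cnga4, Pcp4l1 and Lrrc3b were among the leading genes of the P21 subcluster, and Nqo1 and Cartpt among those of the P0 subcluster. Their differences may thus be those of the libraries.

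Of 17 measured genes of odour transduction, 7 were higher and 0 lower in the P21 library (median log2 change 0.48, percentile 99.99 of random lists). Omp stood at 3799, 4264, 5008 and 6627 CPM (1.74-fold, 1.69 to 1.80), Cngb1, a further channel subunit, was 1.75-fold higher (1.42 to 2.18), and Gfy, needed for odour responses, 1.64-fold (1.57 to 1.72). Of this list, Omp, Gnal, Adcy3, Cnga2, Cnga4, Cngb1, Ano2, Stoml3 and Umodl1 also served as markers of the class. Its percentile is therefore not independent of how cells were named. Of 26 genes of axon guidance and adhesion, 9 were higher and 2 lower (median 0.18, percentile 93.8), among them the ephrin receptors Epha7 (3.89-fold, 2.62 to 6.02) and Epha5 (2.31-fold, 2.02 to 2.65) and the semaphorin Sema7a (3.51-fold, 2.21 to 5.88). Epha5 was among the genes that set the low-depth cluster 1 apart, and Cngb1 among those of a low-depth subcluster; cluster 1 held 22.3% of mature-OSN-like cells at P0 and 42.0% at P21. Against P3 this median was -0.04, against P7 -0.22 and in cluster 1 alone -0.26, all below 0, while that of odour transduction was 0.06 against P7. Of 10 genes known to follow OSN activity, 4 were higher and 2 lower (median 0.36, percentile 98.7). Kirrel2 is in this list too. Lrrc3b was 2.40-fold higher (2.11 to 2.74), Pcp4l1 stood at 756, 866, 1285 and 1748 CPM (2.31-fold, 2.17 to 2.47), and the neuropeptide gene Cartpt at 4892, 4016, 3033 and 2234 CPM (0.457-fold, 0.442 to 0.472). In non-neuronal cells Cartpt was lower at P21 too (96.2 CPM at P0 and 46.9 at P21). Pcp4l1 (75.7 and 72.4 CPM) and Lrrc3b (12.7 and 8.04 CPM) were not higher there. Pcp4l1 and Cartpt were among the genes that set cluster 0 apart.

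Of 20 growth cone and neurite genes, 10 were lower and 1 higher in the P21 library (median -0.65, percentile 0.00). Gap43, Dpysl3, Dpysl5, Crmp1, Stmn2, Stmn4, Tubb3 and Dbn1 of this list also served as markers of the immature class. The percentile is therefore not independent of how cells were named. Gap43 was lower in non-neuronal cells as well, where it stood at 60.1, 70.0, 53.2 and 13.4 CPM (P21 over P0 0.223-fold, 0.103 to 0.430), with a UMI in 8.61% and 2.09% of the thinned cells at P0 and P21. In mature-OSN-like cells 23.3% and 8.40% had one. Marcksl1 (457 and 470 CPM) and Tubb2b (82.0 and 77.7 CPM) were about level there, and how far carried-over RNA of immature OSNs enters the list was not tested. Tubb2a (0.271-fold) and Tubb2b (0.355-fold), beta tubulins of growing neurites, were among them, but each shares a near-identical stretch with a pseudogene and is uncertain. All 4 nuclear factor I genes, transcription factors of neuronal maturation, were measured, and 3 were higher (median 0.61, percentile 99.2). Nfix stood at 163, 196, 284 and 345 CPM (2.11-fold, 1.83 to 2.44). Nfia rested on few counts (3.30-fold, 1.42 to 9.40), and Nfib was 1.51-fold higher (1.08 to 2.14). In the low-depth cluster 1 taken alone, that median was -0.05. Of 16 presynaptic genes 3 were higher (median 0.23, percentile 95.2): the synaptic vesicle proteins Vamp2 (1.74-fold, 1.51 to 2.01) and Sv2a (1.70-fold, 1.12 to 2.67) and the release protein Stx1a (1.56-fold, 1.26 to 1.93). Of 15 genes of receptor choice and trafficking 3 were higher and 2 lower (median 0.14, percentile 87.6). Rtp2, a receptor transporter, was 1.55-fold higher (1.40 to 1.72), and the transcription factor Emx2 was at 0.660-fold (0.534 to 0.819). The 18 cilia genes had 0 higher and 0 lower (median 0.02, and -0.01 with median-of-ratios scaling).

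Dorsal zone markers were both lower: Nqo1, a quinone reductase of dorsal OSNs, stood at 2714, 1898, 1524 and 1131 CPM (0.417-fold, 0.399 to 0.436). Nqo1 was among the genes that set cluster 3 apart, which was kept out of this class and whose share differed by library. How far this enters the difference was not tested. Acsm4 stood at 605, 526, 529 and 345 CPM (0.570-fold, 0.522 to 0.623), and the ventral marker Ncam2 was neither higher nor lower by the list rule (log2 0.37; 1.38-fold, 0.998 to 1.95). Of 14 genes of oxidative phosphorylation 5 were lower and 0 higher (median -0.45, percentile 1.19), such as Ndufa4 (0.502-fold, 0.484 to 0.519) and Sdhb (0.501-fold, 0.464 to 0.541). Of 6 fetal or imprinted genes 3 were lower and 2 higher (median -0.35), led by Ndn (0.0621-fold, 0.0254 to 0.132) and by Igf2bp2 (0.208-fold, 0.103 to 0.403). Ndn was lower in non-neuronal cells too, at 82.7 CPM at P0 and 9.38 at P21. Igf2bp2 stood at 24.0 and 14.7 CPM there, from 34 and 11 UMIs. Of 8 dissociation stress genes 3 were higher and 2 lower (median 0.03, percentile 47.3), with the immediate-early gene Ier2 at 1.77-fold (1.55 to 2.04) and Jund at 0.593-fold (0.554 to 0.636). Jund was lower in non-neuronal cells as well (630 CPM at P0 and 381 at P21), where Ier2 stood at 140 and 107 CPM. Of 3 interferon and MHC class I genes 1 was higher (Ifi27, 4.15-fold, 2.17 to 8.90), 1 lower (B2m, 0.561-fold, 0.441 to 0.714) and 1 neither (median -0.10). Car2, the measured gene of special OSN subtypes, had a log2 difference of 0.00. Of 5 S phase genes, 1 was lower (Gmnn, 0.323-fold, 0.182 to 0.569) and 1 higher (Pcna, 1.92-fold, with a near-identical pseudogene; median 0.30), and the 1 measured G2/M gene, Hmgb2, did not pass (median 0.15).

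RNA from other cells was also seen. Of 8 xenobiotic metabolism genes, which sustentacular and gland cells express, 3 were lower in the mature-OSN-like cells of the P21 library (Gstp1, Cbr2 and Gstm1, each with a near-identical copy; median -0.35, percentile 0.06). Of 3 gland genes 2 were lower, with Bpifa1 at 41.4, 6.59, 3.40 and 7.47 CPM, and 1 was higher, Obp2a, with 0.714 CPM at P0 and 22.4 at P21 (median -0.46). Neither of the 2 measured haemoglobin genes was higher or lower by this rule (median 0.36, percentile 46.0). Col1a1, a collagen of stromal cells, stood at 15.7, 18.0, 11.3 and 0.830 CPM in these cells.

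Of 3519 measured genes, 103 were at least 2-fold higher and 79 at least 2-fold lower in the P21 library, including 23 and 23 odorant receptors. Without receptors these were 80 and 56 of 3466 genes. With an earlier library other than P0, lower genes outnumbered higher ones, with 58 higher and 74 lower against P3 and 45 and 57 against P7. By the naming rule, 18 of the 20 genes at the ends were odorant receptors, none of which led more than 13 cells of a library, and the other 2 were Gm10320 and Fam183b. With receptors left out, the genes with larger levels at P21 included Pth2, a neuropeptide of the parathyroid hormone family (chromosome 7, 45180995 to 45181838), at 54.9, 41.9, 57.7 and 257 CPM (4.68-fold, 3.70 to 5.98), in 451 cells at P21. Bcl2, an inhibitor of cell death (chromosome 1, 106538178 to 106714274), stood at 12.8, 15.6, 31.7 and 83.0 CPM (6.47-fold, 4.02 to 11.1). A second entry for the synaptic scaffold gene Dlg2, listed as Dlg2.1 and not in the annotation under that symbol, stood at 54.9, 120, 112 and 381 CPM (6.93-fold, 5.50 to 8.83). Avp, the vasopressin gene, was 16.3-fold higher (9.23 to 31.7), but 1 cell held 55.9% of its P21 counts. Pth2, Dlg2.1 and Avp were among the leading genes of the subcluster mostly of P21 cells, which may be that library. Exoc6b, of the vesicle-tethering exocyst, was 3.31-fold higher (2.51 to 4.45), and Hist2h4 (4.21-fold), Asap1 (3.94-fold) and Cd27 (3.54-fold) were also higher. Erdr1 was 3.98-fold higher, but at least 2-fold higher in each other class too (3.12-fold in non-neuronal cells, 2.20 to 4.47), and it was not searched for copies.

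At the other end, Fam183b (chromosome 11, 58792797 to 58801960) stood at 505, 176, 121 and 56.7 CPM (0.112-fold, 0.0957 to 0.131). Ly6h (chromosome 15, 75551268 to 75567255) stood at 192, 207, 165 and 28.2 CPM (0.147-fold, 0.116 to 0.185), and the transcription factor Cebpb (chromosome 2, 167688915 to 167690418) at 92.8, 43.7, 47.6 and 12.2 CPM (0.131-fold, 0.0911 to 0.186). Cebpb was also lower in cells outside the neuronal lineage, at 121 CPM at P0 and 20.1 at P21 (0.166-fold, 0.0911 to 0.282). Fam183b (24.0 and 4.02 CPM; 0.167-fold, 0.0329 to 0.532), Ly6h (0.152-fold, 0.0174 to 0.608), Ctnnbip1 (0.505-fold, 0.370 to 0.679), Eif4ebp1 (0.588-fold), Prph (0.211-fold, from 18 and 2 UMIs) and Dmkn (29 and 0 UMIs) were lower in those cells too. Gap43, a marker of immature OSNs, was likewise at 0.223-fold there. For Cebpb, carried-over OSN RNA is argued against. At P0 it stood at 121 CPM there, against 92.8 CPM in mature-OSN-like and 111 CPM in immature-OSN-like cells. Gap43 stood at 60.1 CPM there against 3982 CPM in immature-OSN-like cells. For the other genes, whether they differed outside OSNs or less OSN RNA was carried over at P21 was not tested. In mature-OSN-like cells Dmkn (0.227-fold), E330020D12Rik (0.188-fold), the G protein subunit Gng3 (0.199-fold), Eif4ebp1 (0.273-fold), the intermediate filament gene Prph (0.306-fold) and Ctnnbip1 (0.378-fold) were lower as well. Fam183b, Dmkn and E330020D12Rik were among the leading genes of the subcluster mostly of P0 cells, which may be that library. Ly6h was among the genes that set cluster 3 apart, which was kept out of the class. Highest at P3 or P7 were Gm44791 (47.3 and 51.0 CPM there, 0 UMIs at P21; no entry in the annotation, and in non-neuronal cells likewise 2.83, 15.3, 17.7 and 0 CPM), Pcsk2, a prohormone convertase (17.1, 89.3, 57.7 and 12.2 CPM), Hopx (15.7, 57.5, 65.7 and 9.69 CPM, with a peak at P3 and P7 in non-neuronal cells as well) and the adhesion gene Tenm2 (92.8, 214, 174 and 93.6 CPM). Of the genes the rule names, Gm10320, Gm8730, Gm7658, Tmem181a, Dynlt1a, Sec61g, Rn7sk, Gm10076, Btg1, Gm5514 and Cwc22 have near-identical copies and are uncertain.

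**Figure D2:**
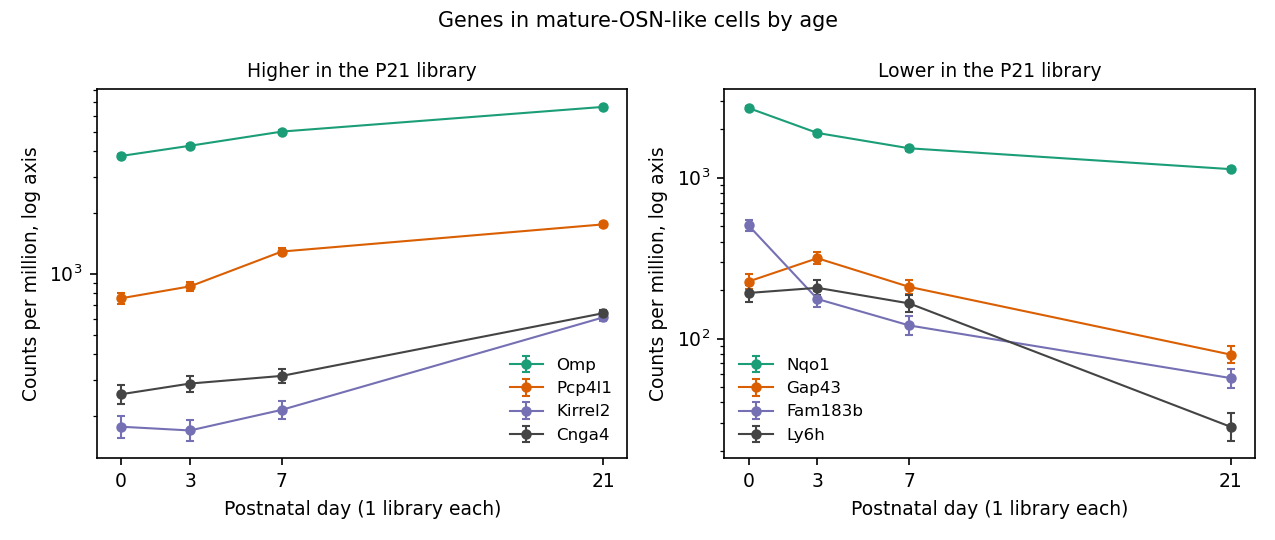
Levels in mature-OSN-like cells (CPM, log axis) against postnatal day for 4 genes higher in the P21 library (Omp, Pcp4l1, Kirrel2, Cnga4) and 4 lower (Nqo1, Gap43, Fam183b, Ly6h), picked after their values were seen, with exact 95% Poisson intervals of 1 library per point. Kirrel2 stays between 169 and 213 CPM up to P7 and stands at 609 at P21, and Fam183b is lower in each later library, from 505 to 56.7 CPM.

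The third comparison concerns immature-OSN-like cells, with 532, 445, 391 and 125 cells and 1764613, 2367989, 1802756 and 692185 UMIs. Gap43 hardly differed between the end libraries (3982, 3606, 3550 and 3854 CPM; 0.968-fold, 0.925 to 1.01). Stmn4, a stathmin that acts on microtubules, stood at 216, 200.2, 189 and 618 CPM (2.86-fold, 2.48 to 3.29). The adhesion gene Ncam1 stood at 978, 1306, 1661 and 1751 CPM (1.79-fold, 1.66 to 1.93) and Ncam2 at 47.6, 51.1, 84.3 and 96.8 CPM (2.03-fold, 1.45 to 2.84). Id2, an inhibitor of helix-loop-helix transcription factors, stood at 58.9, 75.6, 81.5 and 204 CPM (3.46-fold, 2.66 to 4.50), and Cirbp, a cold-inducible RNA-binding protein, at 895, 779, 601 and 407 CPM (0.455-fold, 0.399 to 0.517).

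Of 14 odour transduction genes 5 were higher and 0 lower in the P21 library (median 0.37, percentile 99.9). Gnal, the olfactory G protein, stood at 106, 131, 133 and 267 CPM (2.52-fold, 2.05 to 3.11) and Gfy at 630, 864, 743 and 1263 CPM (fold interval 1.83 to 2.19), against 24.1 and 26.8 CPM at P21 in cells outside the neuronal lineage. Stoml3, of the same list, stood at 116, 57.0, 154 and 383 CPM (3.31-fold, 2.75 to 3.99), but at 114 CPM in non-neuronal cells at P21. Omp stood at 163, 147, 126 and 298 CPM. After thinning, 19.6% (16.2 to 23.3%) of immature-OSN-like cells at P0 and 23.5% (16.2 to 32.2%) at P21 had an Omp UMI. In non-neuronal cells these shares were 12.7% (9.64 to 16.3%) and 17.3% (12.2 to 23.4%), so an Omp share above background was not detectable at P21 at this depth. The level of Omp at P21 was higher in immature-OSN-like cells (298 CPM, 258 to 341) than in non-neuronal cells (138 CPM, 113 to 167). Of 6 activity-dependent genes 3 were higher and 0 lower (median 0.62, percentile 99.95). S100a5 stood at 154 CPM at P0 and 471 at P21, beside 279 and 366 CPM in non-neuronal cells. At P21 1 cell held 23.3% of its counts and 22.7% of those of Pcp4l1 (3.03-fold, 2.20 to 4.19), and Kirrel2 was 3.40-fold higher (1.86 to 6.30). Of 20 growth cone and neurite genes 3 were higher and 1 lower (median 0.16, percentile 98.5), with Dpysl2 at 1.63-fold (1.40 to 1.90) and Mllt11 at 0.564-fold (0.457 to 0.691). Against P3 this median was -0.06, below 0. Markers of the immature class, Gap43 and Stmn4 among them, are part of this list.

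Of 15 genes of receptor choice and trafficking 3 were higher (median 0.18, percentile 97.4), but the median was -0.05 against P3 and -0.06 against P7. The stress-response factor Atf5 stood at 1410, 2655, 2161 and 2514 CPM (1.78-fold, 1.68 to 1.90) and the transcription factor Ebf4 was 1.93-fold higher (1.38 to 2.67). Of 22 axon guidance and adhesion genes 5 were higher and 0 lower (median 0.06, and -0.04 with median-of-ratios scaling). Of 15 presynaptic genes 3 were higher and 1 lower (median 0.16, percentile 88.7), with the synaptic vesicle proteins Syn1 at 2.55-fold (1.37 to 4.75) and Syp at 2.05-fold (1.21 to 3.44). Nfib was 1.83-fold higher (1.29 to 2.57) among 3 nuclear factor I genes (median 0.52, percentile 97.2). Of 5 stress genes 2 were higher (Jun, 1.76-fold, and Hsp90aa1, 1.93-fold, which has a near-identical copy) and 1 lower (Jund, 0.657-fold; median 0.55, percentile 99.1). Both measured interferon genes were higher (Ifi27, 4.67-fold, 2.21 to 10.4, and B2m, 1.54-fold, 1.07 to 2.20; median 0.92). Among 9 fetal or imprinted genes 3 were lower, such as Ndn (0.131-fold, 0.0348 to 0.348), and 1 was higher (median 0.01, and -0.09 with median-of-ratios scaling). Ndn (82.7 CPM at P0 and 9.38 at P21) and Jund (630 and 381 CPM) were lower in non-neuronal cells as well.

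Of 16 cilia genes 2 were higher, Foxj1 (2.27-fold, 1.36 to 3.75) and Ttc8 (1.73-fold, 1.21 to 2.47), and 1 lower, Bbs4 (0.480-fold), which has a near-identical stretch in another gene (median -0.03). Of 14 oxidative phosphorylation genes 1 was lower, Sdhb (0.661-fold, 0.583 to 0.749; median -0.17). Neither dorsal zone gene was higher or lower (median -0.22), and Ncam2, given above, is the ventral list (log2 0.89). Of 7 S phase genes 1 was higher (Pcna, 2.06-fold, with a near-identical pseudogene; median 0.25), and the 1 G2/M gene was neither (0.10). Of 8 xenobiotic genes 3 were lower (median -0.69), and of 3 gland genes 2 (median -0.85; Bpifa1 at 57.2 and 11.6 CPM). Hbb-bs stood at 22.1 and 8.67 CPM (0.392-fold, 0.136 to 0.933). Car2 (3.34 on the log2 scale) rested on 1 cell with 97.6% of its 123 counts at P21.

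Of 3770 measured genes, 74 were at least 2-fold higher and 30 at least 2-fold lower, a share higher of 71.2%. With median-of-ratios scaling the split was 58 and 41 (58.6%), the median gene moving from 0.02 to -0.08, and with the trimmed mean of M values it was 60 and 40. In male cells alone, 176 at P0 and 28 at P21, it turned round to 64 higher and 111 lower (36.6%). Without receptors it was 60 and 27 of 3752 genes. With receptors left out, the named genes with larger levels at P21 included 1700097N02Rik (13.8-fold, 7.39 to 28.1; it overlaps Glo1 and is uncertain), Stom, a membrane protein related to Stoml3 (3.33-fold), Erdr1 (3.31-fold, 2.15 to 5.14), which was higher in each class, and the transcription factor Cebpa (41.4, 77.7, 81.5 and 131 CPM; 3.18-fold, 2.31 to 4.39), which was higher in non-neuronal cells too (4.79-fold, 2.68 to 8.97). The processed pseudogene Gm9847 had 0 UMIs in the earlier libraries and 44 at P21 (63.6 CPM), but likewise 0 and then 36 in mature-OSN-like, 52 in progenitor-like and 9 in non-neuronal cells. It was not searched for copies and is uncertain. Nlrp14 and Fcer1a came from 1 and 2 cells. Lower were Cebpb (111, 49.4, 52.7 and 5.78 CPM; 0.0523-fold, 0.0141 to 0.136), the linker histone H1fx (0.224-fold, and 0.0736-fold in non-neuronal cells), the transcription cofactor Lmo1 (0.177-fold), Mbl2 (0.247-fold), Mir670hg (0.249-fold), Hddc2 (0.322-fold), Dusp26 (0.367-fold) and Wdr83 (0.367-fold).

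Highest at P3 or P7 in these cells were Hopx (17.6, 123, 125 and 43.3 CPM), 2610037D02Rik (74.8, 105, 220 and 92.5 CPM) and, with an overlapping gene, Meg3 (41.9, 87.0, 108 and 1.44 CPM). Meg3 also has a near-identical stretch in another gene, so its values in each class are uncertain. Both 2610037D02Rik and Meg3 led a low-depth subcluster with 93 of its 154 cells from P7. Meg3 was also highest at P3 in non-neuronal cells (331, 867, 552 and 115 CPM), but in progenitor-like cells at P21 (24.9, 58.5, 30.3 and 146 CPM; 5.85-fold over P0, 4.40 to 7.84). Gm37194 rested on 1 cell, and Bglap3 (166, 480, 203 and 34.7 CPM) has a near-identical neighbour and is uncertain. Gm10320, Tpm3-rs7, Gm8730, Gm5436, Gm7658, Gm8624, Dynlt1a, Sec61g, Gm10076, Gm5514 and Acat2 have near-identical copies and are uncertain. In cluster 2 alone, which holds most P21 but few P0 cells (99 and 69), the counts were 144 and 83.

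**Figure D3:**
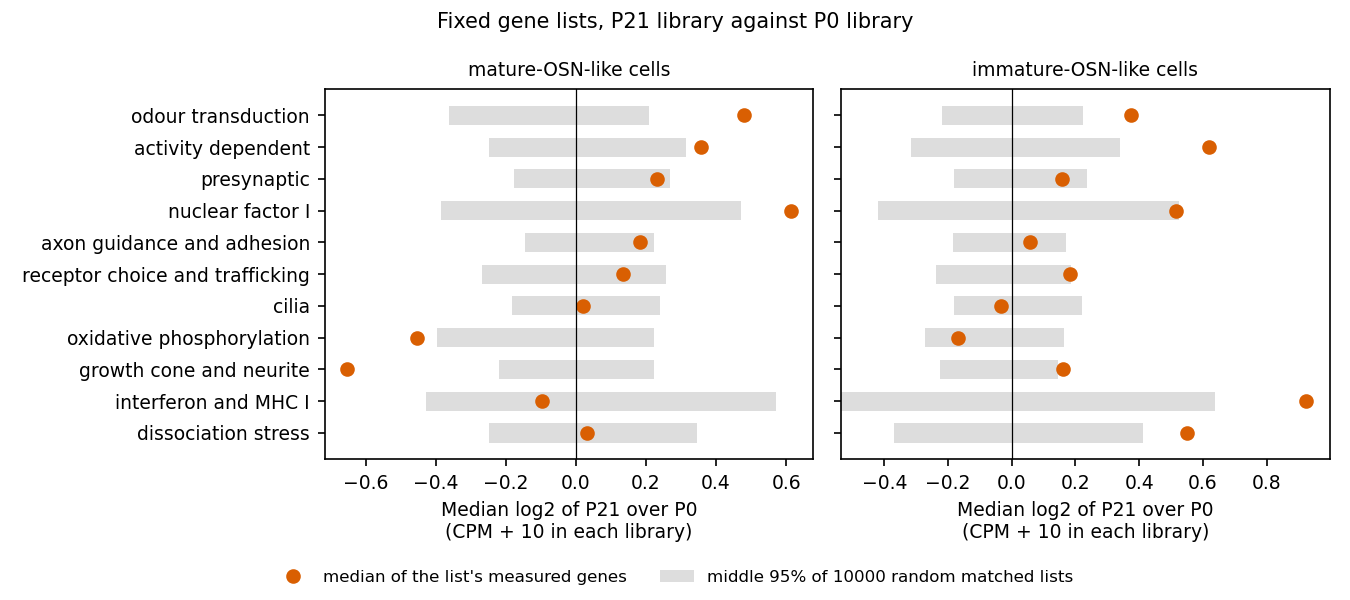
Median log2 of P21 over P0 (horizontal axis, CPM + 10 in each library) of 11 gene lists in mature-OSN-like and immature-OSN-like cells, with points for the lists and grey bars for the middle 95% of 10000 random matched lists. Growth cone genes lie at -0.65 in mature-OSN-like cells and at 0.16 in immature-OSN-like cells; the medians of cilia genes in the first and of axon guidance genes in the second change sign with median-of-ratios scaling.

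Over all cells, where the shares of classes enter every value, the P21 library had more mRNA of mature neurons and less of dividing and stromal cells. All 17 odour transduction genes were higher (median 1.47, percentile 100), with Cnga4 at 5.78-fold (5.27 to 6.34). Of 17 presynaptic genes 11 were higher and 1 lower (median 0.50), as were 13 of 32 axon guidance genes with 2 lower (median 0.37), 6 of 11 activity-dependent genes (median 0.36) and 5 of 18 cilia genes (median 0.18). Of 12 G2/M genes 10 were lower and 0 higher (median -0.62, percentile 0.00), such as Birc5, a mitotic survivin (0.416-fold, 0.355 to 0.486). Of 12 S phase genes 9 were lower and 1 higher (median -0.53). Of 18 fetal and imprinted genes 13 were lower and 0 higher (median -0.58, percentile 0.00). H19, an imprinted RNA (chromosome 7, 142575529 to 142578143), stood at 81.3, 409, 148 and 0.585 CPM (0.00720-fold, 0.00196 to 0.0185). Its neighbour Igf2, a fetal growth factor, stood at 32.1, 109, 68.1 and 1.32 CPM (0.0410-fold, 0.0185 to 0.0789).

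The stromal and mural genes Col1a1 (0.105-fold, 0.0877 to 0.125), Col3a1 (0.122-fold), Sfrp2 (0.0273-fold), Myl9 (0.109-fold) and Acta2 (0.137-fold) and the glial gene Fabp7 (0.0926-fold) were lower, beside 0.779% stromal-like cells at P21. Igfbp3 (14.5, 81.6, 17.2 and 2.05 CPM) and Cthrc1 (19.9, 97.8, 43.3 and 5.12 CPM) were highest at P3. Growth cone genes had 11 lower and 1 higher of 20 (median -0.63), receptor choice genes 5 higher and 3 lower of 15 (median 0.00, and -0.02 with median-of-ratios scaling), nuclear factor I genes 1 higher of 4 (Nfix, 2.75-fold; median 0.18), interferon genes 2 higher and 3 lower of 13 (median -0.05), and stress genes 3 higher and 1 lower of 10 (median 0.00). There were, for oxidative phosphorylation, 2 lower of 14 (median -0.06), for xenobiotic genes 4 higher and 4 lower of 17 (median -0.16), and for gland genes 3 higher and 5 lower of 9 (median -0.86). Of haemoglobin genes 1 was higher of 2 (median 0.12), and of genes of special OSN subtypes 1 higher and 2 lower of 3 (median -0.29). Neither dorsal zone gene was higher or lower (median -0.01), and ventral Ncam2 was 1.58-fold higher (log2 0.51). Of 3779 measured genes 194 were 2-fold higher and 127 lower. Pth2 (12.2-fold), Dlg2.1 (13.9-fold), Lpcat4 (6.12-fold, 5.34 to 7.04), Exoc6b (4.27-fold) and the retinoic acid receptor Rarg (3.62-fold, 3.24 to 4.06) were among the named genes higher at P21. Rbm45, an RNA-binding protein, was lower there (50.8, 42.3, 33.2 and 4.09 CPM; 0.0806-fold, 0.0529 to 0.118), also within mature-OSN-like cells (0.0885-fold) and non-neuronal cells (0.0441-fold, 0.00109 to 0.259).

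The last comparison concerns odorant receptors, of which each mature OSN is known to use 1. After thinning, 68.5% of mature-OSN-like cells at P0 (209 of 305, interval 63.0 to 73.7%), 74.6% at P3 (249 of 334, 69.5 to 79.1%), 75.2% at P7 (267 of 355, 70.4 to 79.6%) and 78.4% at P21 (607 of 774, 75.4 to 81.3%) held a receptor, and 45, 6, 17 and 62 shallower cells were left out. Immature-OSN-like cells held one in 41.5% at P0 (37.2 to 46.0%) and 55.5% at P21 (46.1 to 64.6%), progenitor-like cells in 2.03%, 1.03%, 1.83% and 0.781%, and non-neuronal cells in 0.239%, 0.370%, 0.733% and 0.524%. Unthinned, the mature shares were 82.9%, 80.6%, 81.5% and 85.0%, at median depths of 4450, 3723.5, 4211 and 3887.5 UMIs. In non-neuronal cells they were 0.359%, 0.638%, 0.868% and 0.926%, at 2304, 3723, 3642 and 2591 UMIs. The P21 share exceeded the P0 share by 9.90 points with thinning and by 2.19 without.

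Among all OSNs, 2.32% at P0 (1.52 to 3.39%), 1.74% at P3 (1.03 to 2.73%), 1.52% at P7 (0.789 to 2.64%) and 1.71% at P21 (0.997 to 2.72%) held 2 or more receptors. These intervals overlap, but the pool mixes classes that went different ways. In mature-OSN-like cells the shares were 3.93% at P0 (2.05 to 6.77%), 3.59%, 1.97% and 1.42% at P21 (0.712 to 2.53%). In immature-OSN-like cells they were 1.41% at P0 (0.569 to 2.89%), 0.226% at P3 (1 of 442 cells, 0.00573 to 1.254%), 1.18% at P7 and 5.04% at P21 (6 of 119 cells, 1.87 to 10.7%), and the intervals of P3 and P21 do not overlap. Unthinned they do, with 5.17% at P3 (3.30 to 7.65%) and 9.60% at P21 (5.06 to 16.2%). Doublets could not be removed reliably. Unthinned, the pooled shares were 4.29%, 5.17%, 5.14% and 3.57%. In mature-OSN-like cells the unthinned shares were 6.29% at P0 (3.98 to 9.36%) and 2.63% at P21 (1.66 to 3.96%). Those 2 intervals do not overlap, unlike the thinned ones, but median depth was higher at P0 (4450 against 3887.5 UMIs). Per 100 receptor-positive mature-OSN-like cells, 89, 92, 90 and 91 different receptors led a cell, and 167, 203, 211 and 396 receptors were seen in all. At P21 Olfr536 led 13 of 607 cells (2.14%, 1.15 to 3.63%). All receptor genes together took 6123, 7237, 7878 and 7977 CPM in mature-OSN-like cells and 2674, 2475, 3107 and 3334 CPM in immature-OSN-like cells, unthinned. The median over single receptor genes was 0.87 in mature-OSN-like cells, -1.20 in immature-OSN-like cells, 2.30 in cluster 2 alone and 0.45 in all cells. Since 1 cell can carry a receptor gene into this list, these medians depend on the number of cells per library and are not read as differences in expression. Without the cell with most UMIs of each gene, the median in mature-OSN-like cells was 0.04.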

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

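Alternatives with male cells alone, single clusters, the low-depth clusters left out, the lineage as denominator, other doublet or gene removals, thinned or deep cells in the subclustering, and other scalings of lists over all cells were chosen after the results were seen; all others were fixed before the data were examined. No paired analysis was possible because there was 1 library per age. With 1 library per age no library could be left out, and age cannot be told apart from library under any alternative. The gate gives no progenitor class and so no value for it. Of the alternatives fixed beforehand for the main results, 120 stayed within the interval of the value reported or within 1.5 times a count, 30 moved and 1 reversed, and of the added ones 56 stayed and 18 moved. A reversal was counted only where the interval of the main value excluded no difference, and never for counts of genes. Changes of direction are therefore also among those that stayed or moved. Examples are the axon guidance median of mature-OSN-like cells and their split of higher and lower genes, against P3 and P7. The cause was not tested in any of these except where the alternative itself uses fewer genes or cells.

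The P21 minus P0 difference in the share of mature-OSN-like cells stayed above 0 in each alternative run. It was 24.2 percentage points without the limits on genes, mitochondrial and haemoglobin UMIs, where called doublets stayed removed and cells were clustered and named anew. It was 42.6 at resolution 0.5, 41.1 at resolution 2, 36.3 without the low-depth clusters and 53.3 within the lineage. The difference for immature-OSN-like cells stayed below 0, at -17.8 with stricter cell filters, -17.1 with doublets kept, -18.5 without the highest doublet scores, -16.9 when clustered without genes that differ in stromal-like cells, -19.2 with the gate and -14.8 within the lineage. Progenitor-like cells differed by -31.4 within the lineage and by -22.3 to -26.0 otherwise. The P21 ratio of immature to mature cells over the P0 ratio (0.0984) was 0.139 at resolution 0.5 and 0.149 at resolution 2. The percent of P0 OSNs in subclusters of 1 library was 38.7 at resolution 0.3, 0.447 after thinning, 92.5 for those cells unthinned, 50.7 in male cells alone, and 37.0 without the genes that differ in stromal-like cells.

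In mature-OSN-like cells, the numbers of genes 2-fold higher and lower were 48 and 43 with 50 CPM added, 293 and 210 with no filter, 29 and 27 at 200 CPM or more, and 163 and 131 in male cells. They were 58 and 74 against P3 and 45 and 57 against P7, where lower genes outnumbered higher ones, and 310 and 93 in cluster 1 alone, which had 78 cells at P0. Odour transduction had a median of 0.0596 against P7. Axon guidance and adhesion had -0.22 against P7 and -0.26 in cluster 1, where nuclear factor I had -0.0490. In immature-OSN-like cells the numbers were 37 and 12 with 50 CPM added, 175 and 136 with no filter, 22 and 6 at 200 CPM or more, and 144 and 83 in cluster 2. They were 49 and 25 against P3, 47 and 31 against P7, and 64 and 111 in male cells, of which there were 28 at P21, so that lower genes outnumbered higher ones there. Receptor choice had medians of -0.0461 against P3 and -0.0610 against P7, growth cone genes -0.0570 against P3 and 0.48 in cluster 2, and single odorant receptors, whose median depends on the number of cells, 2.30 in cluster 2.

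The P21 minus P0 difference in the share of mature-OSN-like cells with a receptor (9.90 points) was 2.05 with 1 UMI as the threshold and 2.19 without thinning, and that in OSNs with 2 or more receptors (-0.62) was 2.32 with 1 UMI. Depth limits the immature comparison, since the P21 library has 692185 UMIs in 125 such cells.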

Other observations

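The subclustering without genes that differ in stromal-like cells, its random-gene and deep-cell controls, the copy pairs, the thinned subclusters, the sex of the cells behind the first pattern and depth as the explanation of the low-depth clusters were tested after the results that raised them were seen. A subcluster of 150 OSNs was led by Pcdh11x, Cyp4v3, Tshz1 and the helix-loop-helix genes Olig1 and Olig2, which are known from glial and motor neuron progenitors. Its cells had 2599 CPM of Gap43 and 440.0 CPM of Omp, and there were 60 cells at P0, 51 at P3, 28 at P7 and 11 at P21. These were 4.95% of the OSNs at P0, 4.89% at P3, 3.27% at P7 and 1.03% at P21 (0.517 to 1.84%). Much of that difference lies in the larger number of mature-OSN-like cells at P21, none of which were in this subcluster at any age. Of the immature-OSN-like cells it held 6.20% at P0 (4.31 to 8.60%), 4.49%, 3.84% and 3.20% at P21 (0.879 to 7.99%). Of the cells with both OSN marker sets it held 8.18% at P0 (27 cells, 5.46 to 11.7%) and 11.97% at P3 (31 cells). In that class it held 13.98% at P7 (13 cells, 7.66 to 22.7%) and 6.80% at P21 (7 cells, 2.78 to 13.5%). The intervals of the ages overlap within each of these classes, so no direction with age is read from them. Class I odorant receptors, the family that lies in 1 stretch of chromosome 7 (102476579 to 105369355, 156 genes), led 9.09% of the receptor-positive mature-OSN-like cells at P0 (19 of 209, 5.56 to 13.8%), 13.3% at P3, 15.4% at P7 (11.3 to 20.2%) and 5.60% at P21 (34 of 607, 3.91 to 7.74%). The interval of P21 overlaps that of P0 but not those of P3 (9.30 to 18.1%) and P7. In cells with both OSN marker sets the share was 19.9%, 19.7%, 17.9% and 17.3%, and in immature-OSN-like cells 17.5%, 23.7%, 15.4% and 13.6%.

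Several genes stood apart at the middle ages. Hopx, a homeodomain protein, stood at 7.96 CPM at P0, 27.4 at P3, 80.8 at P7 and 8.98 at P21 in progenitor-like cells, with a peak at P3 or P7 in both OSN classes too. Non-neuronal cells of these libraries shared the peak at a lower level, with 2.12, 8.93, 11.6 and 2.68 CPM from 3, 39, 21 and 2 UMIs. Tenm2, an adhesion protein of synaptic partners, stood at 98.6, 192, 262 and 126 CPM in immature-OSN-like cells. Cirbp was lower in the P21 library in mature-OSN-like cells (0.574-fold), progenitor-like cells (0.410-fold) and, less so, non-neuronal cells (295 CPM at P0 and 236 at P21). Cells with Xist and no Y transcript were 2.24% of the cells with either at P0, 37.7% at P3, 43.9% at P7 and 67.2% at P21, so the libraries also differ in the sex of the cells. Xist overlaps the antisense gene Tsix, so its counts cannot be assigned with certainty.

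The P0 OSNs lay mostly in subclusters of their own (83.7% of 1212), although subclusters of 1 library held only 37.0% of all OSNs. A different sex mix stays open: when male cells alone were clustered, 50.7% of 422 P0 OSNs (45.8 to 55.6%) lay in subclusters of 1 library, between the bounds set for and against it, and there were fewer cells to cluster. Lower depth may account for much of it, since after thinning the percent was 0.447 against 92.5 for the same cells unthinned, but thinning also removes information, and a subcluster of P21 cells remained. A shift of the whole library is another candidate explanation: without 1214 genes that differ between P0 and P3 in stromal-like cells the percent was 37.0, against 49.3 to 84.3 (median 83.5) in 5 draws that left out 1153 random genes of like expression, although the draws held fewer variable genes (140 to 164, against 200). A difference between ages stays open, as untested.

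There were 11 genes, Xist among them, that differed at least 2-fold in the same direction in each class between consecutive libraries. Sex does not account for them as a set, as 12 of 13 such differences other than that of Xist (92.3%) were still at least 1.5-fold in male cells of the mature-OSN-like class and of the non-neuronal cells, the only classes tested so. Reads shared with a near-identical copy may: all of the 10 others (100%, 69.2 to 100%) had such a stretch, against 31.1% of 2190 measured genes, these 10 among them. Of the 11 genes, 7 have the symbol of a pseudogene or predicted gene. Such genes are often copies of another gene, so the high share was partly set by their kind. Rps3a3 stood at 14.8, 655, 556 and 3.22 CPM while Rps3a1, 98.3% identical over 300 bases, stayed at 1576, 1586, 1079 and 1189 CPM, and Gm10320 at 204 CPM at P21 beside 274 CPM of Sec61b, which had 613 CPM at P0. Variants of an outbred strain that send reads to one copy or the other, and age, stay open as untested.

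Low-depth clusters were paired with deeper ones, 1 with 0 in mature-OSN-like cells, 13 with 2 in immature ones and 14 with 9 in progenitors. The last pair does not share a name (immediate neuronal precursor-like and globose basal cell-like), so cell type enters it; the smallest ratios below come from the other pairs. Lower depth alone is argued against, since it would leave shares unchanged, and the nuclear RNA Malat1 took at least 2.005 times the share in each low-depth cluster (12.2% against 6.09% in cluster 1). Cells that lost cytoplasmic RNA are a candidate explanation: other nuclear-retained RNAs (such as Neat1) were higher by a median of 1.67-fold or more in each pair, and ribosomal protein RNA was lower (2.67% against 4.42% in cluster 1), while ribosomal and Malat1 shares had been seen before. The low-depth cluster held 22.3% of mature-OSN-like cells at P0, 53.2% at P3, 58.1% at P7 and 42.0% at P21, so its weight in the mature comparison differs by library. A biological state of the cells stays open, as untested.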
